A study of Rattus norvegicus with 30 samples.

How the data were processed

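RNA levels were measured in primary rat hepatocytes exposed to dioctyl phthalate at 250 or 1000 µM, or to vehicle, for 24 or 48 h. Per the labels, frozen hepatocytes of male Sprague Dawley rats were bought, thawed, plated on collagen, overlaid with Matrigel and dosed on day 3 of culture in 1% DMSO. Each of the 6 groups (vehicle, 250 µM and 1000 µM at each time) held 5 cultures, each 1 separate well with its own array, so there were 30 arrays. The wells came from purchased cells, and the number of animals or vials behind them is not given in the sources used here. The errors therefore describe differences between wells. The series belongs to a set of 10 compounds studied at different times, of which this compound alone was analysed here.

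The deposited values are the authors' intensity signals per probe set on a linear scale, 1 column per array. MAS5, Affymetrix software that scales each array to a common average, is the tool named by the authors, and its version and settings are not given in the sources used here. The mean after trimming 2% at each end was 1500.6 to 1500.7 on the 30 arrays, so the authors' values carry this scaling. Signals were converted to log2 after adding 1. Array medians then lay between 8.44 and 8.78, a span of 0.34 that was under the bound of 0.5 set for further scaling, so none was applied.

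The table held 31099 probe sets. Controls (57) were left out, as was the 40% of probe sets with the lowest mean log2 signal, a limit of 7.88 (signal 234). This left 18625 probe sets, of which 14112 had 1 gene symbol in the platform table. For each gene the probe set with the highest mean was kept, giving 10528 tested genes. The 436 probe sets with several genes and the 9780 without a gene were not used in the gene tests. Genes with no probe set of their own under these rules, Cyp2b1 among them, were not analysed here. Of the 170 genes that the rule selected or that were added to it, 0 had a probe set marked by Affymetrix as shared between transcripts of several genes (_s_at) and 0 one marked for cross-hybridisation (_x_at). Closely related gene copies, such as Acot1 and the other acyl-CoA thioesterases beside it, can still share probe sequence, which was not tested. Arrays measure signal over background, and the number of arrays limits the precision.

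Gene tests used limma 3.58.1 in R 4.3.3, with 1 mean per group over all 30 arrays, 24 residual degrees of freedom and moderated variances with a mean-variance trend. There were 9 contrasts: each dose against vehicle at each time (4), 1000 against 250 µM at each time (2), 48 against 24 h in vehicle (1) and the difference between times in each dose's effect (2). Genes with a Benjamini-Hochberg adjusted p under 0.05 over the tested genes are called changed. Unless stated otherwise, a value after a gene is its log2 change with its standard error from limma, for 5 arrays per group.

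Gene lists (23 lists, 466 entries) were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Adjusted p-values of lists were taken over the 23 lists in each comparison. The lists were peroxisomal beta-oxidation, mitochondrial beta-oxidation and ketogenesis, PPARα-regulated omega-oxidation and lipid handling, drug metabolism regulated by CAR and PXR, AhR targets, NRF2 targets, unfolded protein and integrated stress response, heat shock proteins, p53 targets, cholesterol synthesis, fatty acid synthesis, bile acid synthesis and transport, gluconeogenesis and glucose handling, hepatocyte markers, acute phase response, inflammatory chemokines and NF-kB targets, cell cycle, culture dedifferentiation and cytoskeleton, metallothioneins, and markers of stellate cells, of Kupffer cells and leukocytes, of liver endothelial cells and of cholangiocytes. The comparisons, their main tests, the lists, the rule for named genes and all alternatives but 2 were fixed before the data were examined. Those 2, and the tests of explanations that the closing section marks so, were chosen afterwards.

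The rule named, for each comparison, the changed genes of largest rise and largest fall whose treated arrays all lay on one side of the vehicle arrays: 8 and 8 for 1000 µM against vehicle, 5 and 5 for 250 µM against vehicle and for time in vehicle, 3 and 3 between doses. For the differences between times it took 3 and 3 with no condition on overlap. It added up to 4 changed members of each list with the smallest p and the measured members of a fixed set (Cyp4a1, Ehhadh, Cpt1a, Pdk4, Cyp3a23-3a1, Cyp1a1, Cyp7a1 and Alb). Genes named outside it were chosen after their values were seen and are marked so in the part where they appear.

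Array quality was read from the array median and from the log2 ratio of the 3' to the 5' control probe set of beta-actin and of Gapdh, which rises when RNA or its copies are shortened. Groups were compared with exact two-sided permutation tests over 15 tests. Calls shared between comparisons were counted against the number that independent calls would give. As the doses share vehicle arrays, they were also compared with 20 simulated sets with no effect and with the vehicle arrays split between the doses. A simulation drew independent normal noise for each gene and planted 200 changes at 1000 µM and 24 h in each of 3 runs. Against vehicle the test recovered 62.7% of changes of log2 0.5, 92.0% of changes of log2 1 and 99.5% of changes of log2 2, and 4.87% of its calls were false. The simulated arrays held no variation shared between genes, so these rates may not hold for the real arrays.

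Alternatives were quantile normalization, centring of array medians, pseudocounts of 16 and 64, no filter, a filter of 60%, every probe set on its own, the mean of a gene's probe sets, the 5 sets of consecutive sample numbers as a block, a fit of the compared groups alone, array weights, no mean-variance trend, leaving out each array, and for lists also fry. After the data were seen, 2 more were added: leaving out 4 vehicle arrays at 48 h with a raised actin ratio, and the actin ratio as a covariate. Where 1 vehicle array is left at 48 h, limma assumes that it varies like the arrays of the other groups. Figures were drawn with matplotlib 3.10.9.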

Results

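Primary rat hepatocytes were sampled 24 and 48 h after exposure to dioctyl phthalate, a phthalate diester used to soften plastics, at 250 or 1000 µM, or to vehicle (1% DMSO). The series title gives its question as the effect of this compound on these cells, and its labels as a time course and dose response. There were 30 arrays, 5 in each of 6 groups, 1 per culture well. The correlation of log2 signals between arrays, taken across genes, was 0.968 to 0.986 within groups.

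The beta-actin 3'/5' log2 ratio, a sign of RNA quality, was 1.72 ± 0.494 (SD, n = 5) in vehicle at 48 h and 1.14 ± 0.0841 in vehicle at 24 h (exact permutation p = 0.0397, adjusted p = 0.119 over 15 tests). The other 4 groups had means of 1.14 to 1.30. Replicates 1, 2, 3 and 5 of vehicle at 48 h had ratios of 2.44, 1.74, 1.70 and 1.66, and replicate 4 had 1.04. The Gapdh 3'/5' log2 ratio in vehicle at 48 and 24 h was 0.219 ± 0.0545 and 0.147 ± 0.0216 (SD, n = 5, exact permutation p = 0.0397, adjusted p = 0.119), with means of 0.123 to 0.142 in the other 4 groups. Because of the actin values the counts of changed genes in comparisons with 48 h vehicle are given also without those 4 arrays and with the actin ratio as a covariate, choices made after seeing the data. Leaving out 4 arrays also removes replicates, so the range of counts with each of the 4 as the only vehicle array at 48 h is given beside them. The upper end of each range comes from replicate 1, whose actin ratio lies apart from those of replicates 2, 3 and 5.

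**Figure D1:**
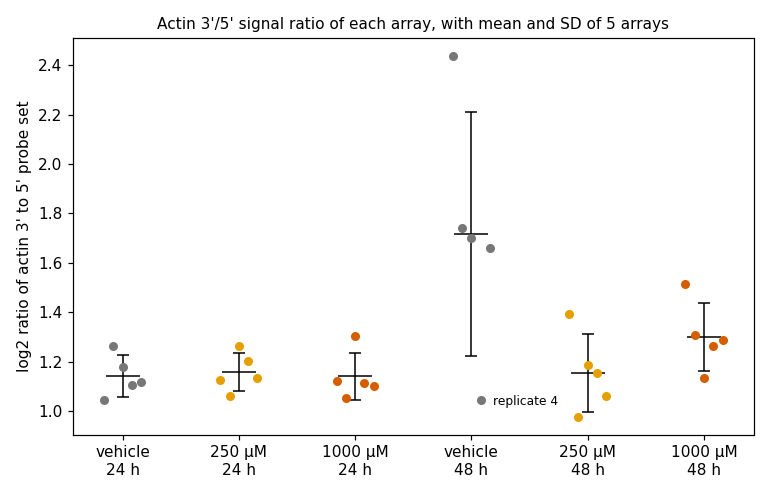
The log2 ratio of the beta-actin 3' to 5' probe set on each array (points), with the mean and SD of 5 arrays per group. In vehicle at 48 h, 4 arrays lie at 1.66 to 2.44 and replicate 4 lies at 1.04.

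After 24 h at 250 µM, genes of fatty acid breakdown rose together. The largest rise was that of Acot1 (7.13 ± 0.24), a cytosolic acyl-CoA thioesterase, though its probe set could read the near-identical copies beside it. Its vehicle signals, 6.67 to 7.41 on the log2 scale, lay under the low-signal limit of 7.88, so its fold is given as a bound against that limit, at least 80.9-fold higher. Ehhadh (3.97 ± 0.14), the bifunctional enzyme of peroxisomal beta-oxidation, was 15.7-fold higher. Pdk4 (2.98 ± 0.12), a kinase that inhibits pyruvate dehydrogenase, Ucp2 (3.64 ± 0.30), a mitochondrial carrier, and Nim1k (3.56 ± 0.44), a protein kinase, rose as well. The largest falls were those of Ccn2 (-3.04 ± 0.10), a secreted matricellular protein, Calml4 (-2.20 ± 0.28), Odad4 (-2.19 ± 0.41), B3galnt1 (-1.83 ± 0.10), a glycosyltransferase, and Steap4 (-1.77 ± 0.11), a metalloreductase. In all, 2030 of 10528 genes changed, 875 upward and 1155 downward (limma), and 160 of them by at least 2-fold. For Ucp2, Nim1k, Calml4 and Odad4 too the lower group had a mean under the limit, and the changes from the limit were 1.82, 1.64, -1.35 and -1.03. Fitted changes that rest on such low signals are not exact, nor is their order.

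All 21 tested genes of mitochondrial beta-oxidation and ketogenesis rose at 250 µM and 24 h (21 adjusted over the list alone), with a median log2 change of 0.81 (camera adjusted p = 2.8e-39, adjusted p = 1.4e-05 with an estimated correlation). They included Cpt1b (2.14 ± 0.09) and Cpt1a (1.13 ± 0.14), which load fatty acids onto carnitine, Acot2 (1.73 ± 0.07) and Acadm (1.13 ± 0.06), the medium-chain acyl-CoA dehydrogenase. Of 16 peroxisomal beta-oxidation genes 13 rose and 0 fell (14 and 0 adjusted over the list alone), with Eci2 (1.39 ± 0.06), Ech1 (1.23 ± 0.06) and Pex11a (1.06 ± 0.05), a peroxisome division protein, among them (camera adjusted p = 8.7e-28, adjusted p = 2.9e-04 with an estimated correlation). Of 25 PPARα-regulated genes of omega-oxidation and lipid handling 21 rose and 1 fell (21 and 1 adjusted over the list alone), and these included Cyp4a1 (2.67 ± 0.08), a fatty acid omega-hydroxylase, Acsl1 (2.05 ± 0.07) and Fabp1 (1.62 ± 0.05), the liver fatty acid-binding protein (camera adjusted p = 1.8e-31, adjusted p = 1.4e-05 with an estimated correlation).

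Of 19 genes of culture dedifferentiation and the cytoskeleton 0 rose and 12 fell (0 and 13 adjusted over the list alone) at 250 µM and 24 h, among them Tpm4 (-0.71 ± 0.05), S100a6 (-0.59 ± 0.08), Tpm1 (-0.34 ± 0.04) and Tubb2a (-0.31 ± 0.05) (camera adjusted p = 5.7e-07, adjusted p = 0.0143 with an estimated correlation). Of 17 acute phase genes 0 rose and 6 fell (0 and 9 adjusted over the list alone), such as Lbp (-1.0 ± 0.08), the lipopolysaccharide-binding protein, Il6r (-0.88 ± 0.12), Serpina3n (-0.61 ± 0.06) and Cp (-0.41 ± 0.08), ceruloplasmin (camera adjusted p = 3.6e-04). Among 11 inflammatory genes 0 rose and 4 fell (0 and 4 adjusted over the list alone), namely Cxcl1 (-1.0 ± 0.18), Cebpd (-0.88 ± 0.19), Tnfaip3 (-0.58 ± 0.08) and Nfkb2 (-0.51 ± 0.15) (camera adjusted p = 0.0144). Of 27 hepatocyte markers 1 rose and 9 fell (1 and 10 adjusted over the list alone), and those that fell included Otc (-0.74 ± 0.11) and Ass1 (-0.63 ± 0.06), enzymes of the urea cycle, Tdo2 (-0.74 ± 0.07) and Proc (-0.39 ± 0.06) (camera adjusted p = 0.00127). Albumin, read by Alb, had a value of -0.04 ± 0.12 and did not pass. Of 20 CAR and PXR regulated genes 8 rose and 3 fell (9 and 3 adjusted over the list alone), with Aldh1a1 (0.78 ± 0.07), Cyp2c6v1 (0.77 ± 0.06) and Ces2c (0.70 ± 0.06) higher and Akr7a3 (-0.35 ± 0.05) lower (camera adjusted p = 0.0186), while Cyp3a23-3a1 (0.07 ± 0.08) did not pass. The calls for the acute phase, inflammatory, hepatocyte and drug metabolism lists were lost with an estimated correlation (adjusted p = 0.115, 0.164, 0.478 and 0.304 with an estimated correlation). With array medians centred the count of changed genes was 1327.

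At 1000 µM and 24 h the largest rises were again those of Acot1 (6.75 ± 0.24) and Ehhadh (3.83 ± 0.14), followed by Nim1k (3.52 ± 0.44), Ucp2 (2.92 ± 0.30), Pdk4 (2.81 ± 0.12), Cyp4a1 (2.72 ± 0.08), Lrrc39 (2.42 ± 0.09) and Dnajb3 (2.39 ± 0.37). The largest falls were those of Calml4 (-2.92 ± 0.28), Ccn2 (-2.84 ± 0.10), Hao2 (-1.75 ± 0.08), a peroxisomal hydroxyacid oxidase, B3galnt1 (-1.72 ± 0.10), Acta1 (-1.63 ± 0.15), an actin of muscle, and Steap4 (-1.62 ± 0.11), Cdr2 (-1.48 ± 0.21) and Tsx (-1.40 ± 0.23). 2051 of 10528 genes changed, 872 upward and 1179 downward (limma), and 136 of them by at least 2-fold. With array medians centred the count was 1284, with 677 upward and 607 downward. A lower group under the low-signal limit of 7.88 makes the fitted changes of 6 of the named genes inexact. From the limit they were 5.97 for Acot1, 1.59 for Nim1k, 1.09 for Ucp2, 0.97 for Dnajb3, -1.35 for Calml4 and 0.84 for Cdc20.

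The same 3 fatty acid lists passed at 1000 µM and 24 h. All 21 mitochondrial genes rose (21 adjusted over the list alone; camera adjusted p = 3.4e-40, adjusted p = 1.2e-05 with an estimated correlation). Cpt1b (1.97 ± 0.09), Acot2 (1.62 ± 0.07), Acadm (1.15 ± 0.06) and Cpt1a (1.01 ± 0.14) were among them. In the peroxisomal list 13 rose and 0 fell (14 and 0 adjusted over the list alone) of 16 (camera adjusted p = 4.6e-28, adjusted p = 2.7e-04 with an estimated correlation). Eci2 (1.31 ± 0.06), Ech1 (1.18 ± 0.06) and Pex11a (1.02 ± 0.05) were among them. In the PPARα list 21 rose and 1 fell (21 and 1 adjusted over the list alone) of 25 (camera adjusted p = 7.0e-33, adjusted p = 1.0e-05 with an estimated correlation). Acsl1 (1.89 ± 0.07) and Fabp1 (1.58 ± 0.05) were among them. Dedifferentiation and cytoskeleton genes fell, 12 of 19 (14 adjusted over the list alone; camera adjusted p = 1.1e-06, adjusted p = 0.0173 with an estimated correlation), for example Tpm4 (-0.63 ± 0.05), S100a6 (-0.56 ± 0.08), Tpm1 (-0.29 ± 0.04) and Tubb2a (-0.29 ± 0.05). Of 17 acute phase genes 0 rose and 5 fell (0 and 7 adjusted over the list alone) (camera adjusted p = 5.3e-05). Those named are Lbp (-1.06 ± 0.08), Il6r (-0.77 ± 0.12), Serpina3n (-0.62 ± 0.06) and Cp (-0.48 ± 0.08). Of 11 inflammatory genes 0 rose and 4 fell (0 and 5 adjusted over the list alone) (camera adjusted p = 0.0366). Those named are Cxcl1 (-0.94 ± 0.18), Cebpd (-0.73 ± 0.19), Tnfaip3 (-0.52 ± 0.08) and Nfkb2 (-0.51 ± 0.15). Of 27 hepatocyte markers 1 rose and 10 fell (1 and 11 adjusted over the list alone) (camera adjusted p = 4.4e-04). Those named are Tdo2 (-0.71 ± 0.07), Ass1 (-0.64 ± 0.06), Cebpa (-0.47 ± 0.07) and Proc (-0.34 ± 0.06). The last 3 calls were lost with an estimated correlation (adjusted p = 0.0636, 0.258 and 0.412 with an estimated correlation). Of 20 CAR and PXR regulated genes 7 rose and 3 fell (7 and 3 adjusted over the list alone), but the list did not pass (camera adjusted p = 0.0799). Its members included Aldh1a1 (0.83 ± 0.07), Cyp2c6v1 (0.78 ± 0.06), Ces2c (0.76 ± 0.06) and Akr7a3 (-0.37 ± 0.05), while Cyp3a23-3a1 (0.09 ± 0.08) and Alb (-0.12 ± 0.12) of the hepatocyte markers did not pass.

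The other lists did not pass camera at 24 h at either dose. In what follows the counts are for 250 and then 1000 µM, each with the count adjusted over the list alone in parentheses. Of 16 bile acid genes 4 rose and 9 fell (4 and 9), and 4 rose and 5 fell (4 and 6) (camera adjusted p = 0.124 and 0.473). Cyp7a1 (-1.0 ± 0.13), the rate-limiting enzyme of bile acid synthesis, and Cyp27a1 (-0.64 ± 0.08) fell at 1000 µM, and Abcg5 (0.96 ± 0.14), a sterol transporter, and Nr1h4 (0.69 ± 0.07), the bile acid receptor, rose. Of 14 glucose genes 4 rose and 6 fell (4 and 8), and 4 rose and 6 fell (4 and 7) (camera adjusted p = 0.411 and 0.267). At 1000 µM Tat (-1.13 ± 0.07) and Igfbp1 (-0.53 ± 0.07) fell and Gys2 (0.87 ± 0.08) and Fbp1 (0.51 ± 0.06) rose. Of 18 fatty acid synthesis genes 7 rose and 7 fell (8 and 7), and 6 rose and 7 fell (8 and 7) (camera adjusted p = 0.865 and 0.514). At 1000 µM Elovl6 (0.99 ± 0.09) and Dgat1 (0.86 ± 0.07) rose and Pnpla3 (-1.39 ± 0.17) and Pklr (-0.77 ± 0.10) fell. Of 20 cholesterol synthesis genes 3 rose and 5 fell (3 and 6), and 4 rose and 3 fell (5 and 4) (camera adjusted p = 0.737 and 0.473). At 1000 µM Hsd17b7 (0.67 ± 0.09) and Sc5d (0.44 ± 0.06) rose and Tm7sf2 (-0.42 ± 0.07) and Sqle (-0.39 ± 0.06) fell.

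Among stress lists at 24 h, of 19 NRF2 targets 2 rose and 5 fell (2 and 5), and 2 rose and 5 fell (2 and 5) (camera adjusted p = 0.332 and 0.149). At 1000 µM Gsta4 (0.58 ± 0.05) rose and Gstp1 (-0.92 ± 0.06), Slc7a11 (-0.67 ± 0.09) and Srxn1 (-0.52 ± 0.07) fell. Of 25 unfolded protein and integrated stress genes 2 rose and 5 fell (2 and 5), and 1 rose and 7 fell (3 and 8) (camera adjusted p = 0.677 and 0.207). At 1000 µM Atf3 (-0.62 ± 0.12), Hsp90b1 (-0.39 ± 0.06) and Edem1 (-0.35 ± 0.06) fell and Psat1 (0.29 ± 0.05) rose. Of 11 heat shock genes 1 rose and 2 fell (2 and 4), and 1 rose and 2 fell (1 and 4) (camera adjusted p = 0.912 and 0.892). At 1000 µM Hspb1 (-0.51 ± 0.11) and Hspa1a (-0.28 ± 0.09) fell and Dnaja1 (0.23 ± 0.05) rose. Of 15 p53 targets 2 rose and 4 fell (3 and 6), and 1 rose and 5 fell (2 and 5) (camera adjusted p = 0.151 and 0.192). At 1000 µM Sesn1 (-1.26 ± 0.11) and Ccng1 (-0.54 ± 0.06) fell. Of 5 AhR targets 0 rose and 3 fell (1 and 3), and 1 rose and 3 fell (1 and 3) (camera adjusted p = 0.193 and 0.192). At 1000 µM Cyp1a1 (-0.41 ± 0.11), Cyp1a2 (-0.30 ± 0.08) and Nfe2l2 (-0.34 ± 0.05) fell and Tiparp (0.28 ± 0.09) rose. Of 5 metal response genes 0 rose and 1 fell (0 and 3), and 0 rose and 2 fell (0 and 2) (camera adjusted p = 0.0725 and 0.111). Of 17 cell cycle genes 1 rose and 0 fell (1 and 0), and 2 rose and 0 fell (1 and 0) (camera adjusted p = 0.294 and 0.192), with Ccnd1 (1.11 ± 0.11), cyclin D1, and Cdc20 (1.10 ± 0.37) higher.

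Markers of other liver cell types at 24 h changed in few genes. Of 10 stellate cell and myofibroblast markers 0 rose and 2 fell (0 and 2), and 0 rose and 2 fell (0 and 2), the falls being those of Vim (-1.19 ± 0.09) and Acta2 (-0.46 ± 0.14) at 1000 µM (camera adjusted p = 0.457 and 0.514). Of 10 Kupffer cell and leukocyte markers 0 rose and 0 fell (0 and 0), and 0 rose and 0 fell (0 and 0) (camera adjusted p = 0.912 and 0.892). Of 7 endothelial markers 1 rose and 0 fell (1 and 0), and 0 rose and 0 fell (0 and 0) (camera adjusted p = 0.291 and 0.275). Of 4 cholangiocyte markers 0 rose and 0 fell (0 and 0), and 0 rose and 0 fell (0 and 0) (camera adjusted p = 0.781 and 0.892). Tested markers are those whose mean signal in these cultures passed the filter on low values. At 24 h the sign of the median differed from that of the camera test for heat shock proteins and stellate markers at both doses and for the cell cycle at 250 µM, and median and mean differed in sign in these cases and for fatty acid synthesis at 250 µM (0.04 and -0.03).

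**Figure D2:**
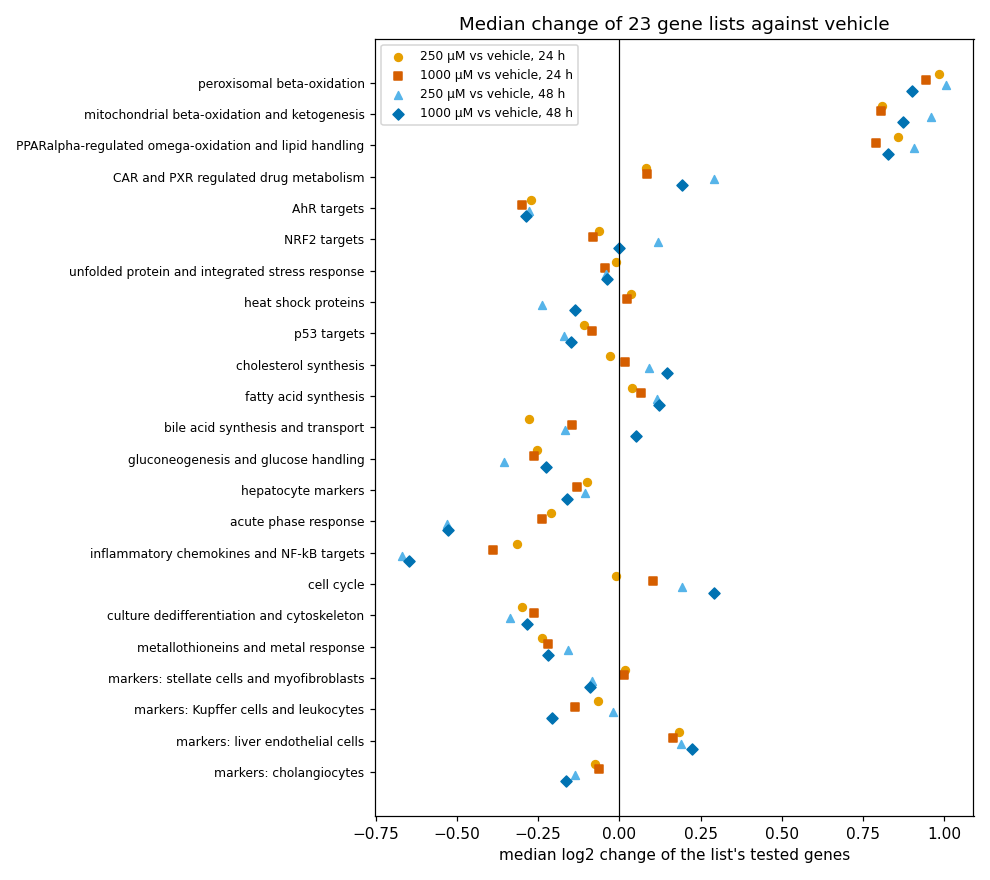
Median log2 change against vehicle of the tested genes of each of 23 lists, with 1 marker per dose and time. The 3 fatty acid lists lie at 0.79 to 1.01 in the 4 comparisons, and the inflammatory list lies at -0.67 to -0.31.

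At 48 h and 250 µM the largest rises were those of Acot1 (6.68 ± 0.24), Ehhadh (3.66 ± 0.14), Spc24 (3.64 ± 0.09), a member of the Ndc80 kinetochore complex, Nim1k (3.55 ± 0.44) and Fabp3 (2.80 ± 0.30), a fatty acid-binding protein. The largest falls were those of Il1r2 (-4.13 ± 0.27), a decoy receptor for interleukin-1, and Ccn2 (-3.15 ± 0.10), Steap4 (-2.56 ± 0.11), B3galnt1 (-2.10 ± 0.10) and Rab11fip5 (-1.96 ± 0.12). 4342 of 10528 genes changed, 1604 upward and 2738 downward (limma), and 310 of them by at least 2-fold. Every probe set tested on its own gave 6556 calls. The actin ratio was 1.15 ± 0.157 in this group and 1.72 ± 0.494 in its vehicle (SD, n = 5, exact permutation p = 0.0397, adjusted p = 0.119), and the Gapdh ratio 0.131 ± 0.0443 and 0.219 ± 0.0545 (SD, n = 5, exact permutation p = 0.0238, adjusted p = 0.119). Without the 4 vehicle arrays of raised ratio fewer genes changed, in about equal numbers up and down, but 1 vehicle array was then left. With each of the 4 as the only vehicle array the count was 2194 to 3034. With the ratio as a covariate it was 2782, with 1153 upward and 1629 downward. Il1r2 lay at 5.81 to 8.29 in the treated arrays, 4 of 5 under the low-signal limit of 7.88. Its change to the limit was -3.20, and those of Fabp3 and Nim1k from the limit, under which their vehicle means lay, were 2.48 and 1.98.

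All 21 mitochondrial beta-oxidation genes rose at 250 µM and 48 h (21 adjusted over the list alone). Pdk4 (2.69 ± 0.12), Cpt1b (2.39 ± 0.09), Acot2 (1.65 ± 0.07), Acadm (1.44 ± 0.06) and Cpt1a (1.01 ± 0.14) were among them (camera adjusted p = 5.3e-31, adjusted p = 8.9e-05 with an estimated correlation). All 16 peroxisomal genes rose (16 adjusted over the list alone). Acot8 (1.63 ± 0.07), Eci2 (1.40 ± 0.06) and Crot (1.28 ± 0.06) were among them (camera adjusted p = 4.1e-23, adjusted p = 9.0e-04 with an estimated correlation). In the PPARα list 22 rose and 1 fell (22 and 1 adjusted over the list alone) of 25 (camera adjusted p = 5.6e-23, adjusted p = 8.9e-05 with an estimated correlation), with Fabp1 (2.64 ± 0.05), Cyp4a1 (2.24 ± 0.08), Aqp7 (2.15 ± 0.07) and Acsl1 (1.93 ± 0.07), where Aqp7 is a glycerol channel. Without the 4 vehicle arrays 20, 13 and 20 members of these 3 lists rose, and each list passed (adjusted p = 1.1e-05, 2.8e-04 and 2.1e-06 with an estimated correlation). Of 19 dedifferentiation and cytoskeleton genes 0 rose and 11 fell (0 and 11 adjusted over the list alone) (camera adjusted p = 3.7e-05, adjusted p = 0.0497 with an estimated correlation). Flna (-1.64 ± 0.18), S100a6 (-1.59 ± 0.08), Tpm4 (-0.98 ± 0.05) and Tpm1 (-0.33 ± 0.04) were among them. Another probe set of Tpm1 was called at -0.473, while its remaining ones were not called and ran from -0.517 to 0.655. Without those arrays 10 fell. Of 17 acute phase genes 2 rose and 11 fell (2 and 11 adjusted over the list alone). A2m (-1.34 ± 0.09), Lbp (-1.27 ± 0.08), Serpina3n (-1.12 ± 0.06) and Cp (-0.98 ± 0.08) were among them. Without those arrays 9 fell. Of 11 inflammatory genes 0 rose and 7 fell (0 and 7 adjusted over the list alone). Icam1 (-1.02 ± 0.15), Nfkb2 (-0.99 ± 0.15), Tnfaip3 (-0.83 ± 0.08) and Cxcl1 (-0.82 ± 0.18) were among them. Without those arrays 3 fell, where Icam1 (-0.72) and Nfkb2 (-0.70) no longer passed. Of 20 CAR and PXR regulated genes 12 rose and 4 fell (12 and 4 adjusted over the list alone). Cyp3a2 (1.82 ± 0.09), Cyp2c6v1 (1.18 ± 0.06), Ces2c (1.06 ± 0.06) and Aldh1a1 (0.87 ± 0.07) were among them. At both doses the value of Cyp3a2 goes with its fall with time in vehicle, given below. Without those arrays 9 rose. Cyp3a23-3a1 (0.26 ± 0.08) of that list rose but did not pass without the 4 arrays (0.18). Of 20 cholesterol synthesis genes 9 rose and 2 fell (9 and 2 adjusted over the list alone). Msmo1 (0.59 ± 0.07), Insig1 (0.44 ± 0.05), Nsdhl (0.43 ± 0.05) and Fdft1 (0.41 ± 0.06) were among them. Without those arrays 5 rose, where Msmo1 (0.33) did not pass. These 4 lists passed at the preset correlation (camera adjusted p = 5.9e-04, 0.0153, 6.2e-04 and 0.00278) and not with an estimated correlation over all 30 arrays (adjusted p = 0.0996, 0.140, 0.0996 and 0.0996). The CAR and PXR list passed with an estimated correlation without the 4 arrays (adjusted p = 0.0421) and with the actin covariate (0.0268), and the other 3 did not.

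At 48 h and 1000 µM the largest rises were those of Acot1 (6.18 ± 0.24), Ehhadh (3.52 ± 0.14), Spc24 (3.25 ± 0.09), Nim1k (3.16 ± 0.44), Fabp3 (2.59 ± 0.30), Pdk4 (2.54 ± 0.12), Pkhd1l1 (2.45 ± 0.20) and Fabp1 (2.36 ± 0.05). The largest falls were those of Il1r2 (-3.31 ± 0.27), Ccn2 (-2.74 ± 0.10), Steap4 (-2.17 ± 0.11), B3galnt1 (-1.81 ± 0.10), Npy (-1.76 ± 0.14), neuropeptide Y, Ampd3 (-1.76 ± 0.22), an AMP deaminase, Gucy2c (-1.67 ± 0.12), a guanylate cyclase receptor, and Cdr2 (-1.65 ± 0.21). 3132 of 10528 genes changed, 1207 upward and 1925 downward (limma), and 199 of them by at least 2-fold. The actin ratio was 1.30 ± 0.137 in this group against 1.72 ± 0.494 in vehicle (SD, n = 5, exact permutation p = 0.111, adjusted p = 0.272), and the Gapdh ratio was 0.142 ± 0.0369 and 0.219 ± 0.0545 (SD, n = 5, exact permutation p = 0.0397, adjusted p = 0.119). Without the 4 vehicle arrays 1177 genes changed, 617 upward and 560 downward, and with each of the 4 as the only vehicle array 1311 to 2199. With the ratio as a covariate it was 2315, with 992 upward and 1323 downward. Counted from the low-signal limit, under which the mean of the lower group lay, the changes were -3.20 for Il1r2, 2.27 for Fabp3, 1.58 for Nim1k and 2.40 for Pkhd1l1.

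The 3 fatty acid lists passed again at 1000 µM and 48 h. All 21 mitochondrial genes rose (21 adjusted over the list alone). Cpt1b (2.34 ± 0.09), Acot2 (1.52 ± 0.07), Acadm (1.30 ± 0.06) and Cpt1a (0.92 ± 0.14) were among them (camera adjusted p = 1.6e-34, adjusted p = 3.8e-05 with an estimated correlation). In the peroxisomal list 14 rose and 0 fell (15 and 0 adjusted over the list alone) of 16 (camera adjusted p = 1.7e-25, adjusted p = 5.1e-04 with an estimated correlation). Acot8 (1.40 ± 0.07), Eci2 (1.24 ± 0.06) and Pex11a (0.88 ± 0.05) were among them. In the PPARα list 21 rose and 1 fell (21 and 1 adjusted over the list alone) of 25 (camera adjusted p = 2.4e-26, adjusted p = 3.8e-05 with an estimated correlation). Cyp4a1 (2.13 ± 0.08) and Aqp7 (1.96 ± 0.07) were among them. Without the 4 vehicle arrays 19, 12 and 18 members rose (adjusted p = 2.4e-05, 5.0e-04 and 2.5e-06 with an estimated correlation). Of 19 dedifferentiation and cytoskeleton genes 0 rose and 15 fell (0 and 15 adjusted over the list alone) (camera adjusted p = 2.8e-07, adjusted p = 0.0117 with an estimated correlation). S100a6 (-1.61 ± 0.08), Tpm4 (-0.74 ± 0.05), S100a10 (-0.42 ± 0.05) and Tpm1 (-0.30 ± 0.04) were among them. Without those arrays 7 fell. Of 17 acute phase genes 1 rose and 11 fell (1 and 12 adjusted over the list alone) (camera adjusted p = 5.1e-06, adjusted p = 0.0321 with an estimated correlation). Lbp (-1.14 ± 0.08), A2m (-1.02 ± 0.09), Serpina3n (-0.95 ± 0.06) and Cp (-0.78 ± 0.08) were among them. Without those arrays 7 fell. Of 20 cholesterol synthesis genes 9 rose and 2 fell (10 and 2 adjusted over the list alone) (camera adjusted p = 2.8e-04, adjusted p = 0.0421 with an estimated correlation). Msmo1 (0.55 ± 0.07), Insig1 (0.46 ± 0.05), Idi1 (0.45 ± 0.06) and Fdft1 (0.40 ± 0.06) were among them. Without those arrays 7 rose (adjusted p = 0.0943 with an estimated correlation), where Msmo1 (0.29) and Idi1 (0.21) did not pass. Of 11 inflammatory genes 0 rose and 6 fell (0 and 8 adjusted over the list alone) (camera adjusted p = 0.00245). Cxcl1 (-1.19 ± 0.18), Icam1 (-0.88 ± 0.15), Tnfaip3 (-0.82 ± 0.08) and Nfkb2 (-0.74 ± 0.15) were among them. Without those arrays 3 fell, where Icam1 (-0.58) and Nfkb2 (-0.45) did not pass. Of 20 CAR and PXR regulated genes 10 rose and 5 fell (10 and 6 adjusted over the list alone) (camera adjusted p = 0.00127). Cyp3a2 (1.73 ± 0.09), Cyp2c6v1 (1.06 ± 0.06), Ces2c (0.97 ± 0.06) and Aldh1a1 (0.75 ± 0.07) were among them. Without those arrays 7 rose. Of 27 hepatocyte markers 1 rose and 11 fell (1 and 11 adjusted over the list alone), with Tdo2 (-0.76 ± 0.07), Ass1 (-0.76 ± 0.06) and Ahsg (-0.74 ± 0.07) lower and Asgr1 (0.71 ± 0.06), an asialoglycoprotein receptor, higher (camera adjusted p = 0.00214), and 7 fell without the 4 arrays. Of 17 cell cycle genes 2 rose and 0 fell (2 and 0 adjusted over the list alone), namely Ccnd1 (1.0 ± 0.11) and Tk1 (0.59 ± 0.08) (camera adjusted p = 0.0474), and 3 rose and 1 fell without the 4 arrays. The last 4 calls were lost with an estimated correlation (adjusted p = 0.0820, 0.131, 0.464 and 0.146 with an estimated correlation). That of the cell cycle was lost at the preset correlation too without the 4 arrays (adjusted p = 0.307) and with the actin covariate (0.110). The CAR and PXR list passed with an estimated correlation with the covariate (adjusted p = 0.0341) and not without the 4 arrays (0.0552). Cyp3a23-3a1 (0.14 ± 0.08) and Alb (-0.01 ± 0.12) did not pass.

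With all 30 arrays the remaining lists did not pass camera at 48 h at either dose, and their counts are given for 250 and then 1000 µM, with those adjusted over the list alone in parentheses. Of 16 bile acid genes 5 rose and 8 fell (6 and 8), and 5 rose and 5 fell (5 and 6) (camera adjusted p = 0.617 and 0.931). At 1000 µM Cyp7a1 (-1.33 ± 0.13) and Cyp27a1 (-0.70 ± 0.08) fell and Abcg5 (1.42 ± 0.14) and Nr1h4 (0.61 ± 0.07) rose. Of 14 glucose genes 3 rose and 9 fell (3 and 9), and 3 rose and 6 fell (4 and 6) (camera adjusted p = 0.489 and 0.474), with Tat (-0.91 ± 0.07) and Igfbp1 (-0.54 ± 0.07) lower at 1000 µM and Pck1 (1.66 ± 0.18), a key enzyme of gluconeogenesis, higher at 250 µM. Of 18 fatty acid synthesis genes 8 rose and 7 fell (8 and 7), and 8 rose and 5 fell (9 and 5) (camera adjusted p = 0.238 and 0.0645), with Fads1 (1.34 ± 0.13) and Fads2 (1.32 ± 0.15), fatty acid desaturases, and Elovl6 (0.88 ± 0.09) and Dgat1 (0.77 ± 0.07) higher at 1000 µM and Acaca (-0.65 ± 0.07), acetyl-CoA carboxylase, lower at 250 µM. The other probe set of Acaca was not called at 250 µM, with 0.0957. Of 19 NRF2 targets 8 rose and 5 fell (8 and 6), and 5 rose and 4 fell (5 and 5) (camera adjusted p = 0.207 and 0.611). At 1000 µM Gsta4 (0.83 ± 0.05) rose and Slc7a11 (-1.06 ± 0.09), Gstp1 (-0.84 ± 0.06) and Srxn1 (-0.66 ± 0.07) fell. Of 15 p53 targets 2 rose and 8 fell (2 and 8), and 2 rose and 6 fell (2 and 7) (camera adjusted p = 0.0919 and 0.131). At 1000 µM Ccng1 (-0.88 ± 0.06), Sesn1 (-0.87 ± 0.11) and Aen (-0.44 ± 0.08) fell. Of 25 unfolded protein and integrated stress genes 5 rose and 8 fell (5 and 8), and 3 rose and 8 fell (3 and 8) (camera adjusted p = 0.970 and 0.519). Of 11 heat shock genes 2 rose and 6 fell (2 and 6), and 1 rose and 5 fell (1 and 5) (camera adjusted p = 0.434 and 0.174). At 1000 µM Cryab (-0.75 ± 0.08) and Hspb1 (-0.65 ± 0.11) fell.

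At 48 h, of 27 hepatocyte markers 1 rose and 10 fell (1 and 10) at 250 µM, where the list did not pass (camera adjusted p = 0.176), and Alb (0.10 ± 0.12) did not pass either. Of 17 cell cycle genes 2 rose and 0 fell (2 and 0) at 250 µM, namely Ccnd1 (0.95 ± 0.11) and Tk1 (0.79 ± 0.08) (camera adjusted p = 0.107). Of 5 AhR targets 0 rose and 3 fell (1 and 3), and 1 rose and 3 fell (1 and 3) (camera adjusted p = 0.238 and 0.210), with Cyp1a2 (-0.59 ± 0.08) and Nfe2l2 (-0.34 ± 0.05) and Cyp1a1 (-0.29 ± 0.11) lower at 1000 µM, the last not past the threshold without the 4 arrays (-0.39). Of 5 metal response genes 1 rose and 2 fell (1 and 2), and 1 rose and 2 fell (1 and 2) (camera adjusted p = 0.600 and 0.524), and the zinc exporter gene Slc30a1 (0.81 ± 0.18), higher at 1000 µM, had -0.13 without the 4 arrays. Of 10 stellate markers 2 rose and 2 fell (2 and 2), and 1 rose and 3 fell (1 and 3) (camera adjusted p = 0.600 and 0.399). At 1000 µM Vim (-1.41 ± 0.09) and Lox (-0.94 ± 0.16) fell. Of 10 Kupffer cell and leukocyte markers 1 rose and 0 fell (1 and 0), and 1 rose and 1 fell (1 and 1) (camera adjusted p = 0.540 and 0.931). Of 7 endothelial markers 2 rose and 0 fell (2 and 0), and 0 rose and 0 fell (0 and 0) (camera adjusted p = 0.182 and 0.251). Of 4 cholangiocyte markers 0 rose and 1 fell (0 and 1), and 0 rose and 1 fell (0 and 2) (camera adjusted p = 0.600 and 0.519). At 48 h median and test differed in sign for the unfolded protein list and the Kupffer markers at 250 µM and for NRF2 targets at 1000 µM, and mean and median for bile acid genes at 1000 µM (-0.02 and 0.05).

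Under the 2 alternatives chosen after seeing the data, 2 of the remaining lists passed at 48 h. The p53 targets passed downward at 250 µM with the actin covariate (camera adjusted p = 0.0226, adjusted p = 0.0394 with an estimated correlation) and without the 4 vehicle arrays (0.0340 and 0.0580). Fatty acid synthesis passed upward at 250 µM (0.0438 and 0.241 with the covariate, 0.00511 and 0.0580 without the arrays) and at 1000 µM (0.00606 and 0.0896, 2.7e-04 and 0.0217). Members that rose and fell without the 4 arrays, at 250 and then 1000 µM, were 2 up with 4 down and 1 up with 4 down for p53 targets, 8 up with 2 down and 7 up with 0 down for fatty acid synthesis, 1 up with 2 down and 1 up with 2 down for the unfolded protein list, 0 up with 2 down and 1 up with 2 down for heat shock, 4 up with 5 down and 4 up with 3 down for bile acids, 4 up with 4 down and 4 up with 4 down for glucose, and 5 up with 3 down and 4 up with 3 down for NRF2. With the covariate they were 2 up with 8 down and 2 up with 5 down, 8 up with 5 down and 8 up with 3 down, 3 up with 5 down and 4 up with 8 down, 2 up with 3 down and 1 up with 3 down, 5 up with 6 down and 4 up with 5 down, 4 up with 7 down and 4 up with 6 down, and 6 up with 3 down and 5 up with 3 down in the same order. With the covariate the fatty acid lists had 21, 15 and 22 mitochondrial, peroxisomal and PPARα members higher at 250 µM and 21, 14 and 21 at 1000 µM. Members lower were 12 and 11 in the dedifferentiation list, 10 and 11 in the acute phase list and 6 and 6 in the inflammatory list at 250 and 1000 µM. Members higher were 10 and 9 in the CAR and PXR list and 9 and 9 in cholesterol synthesis.

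**Figure D3:**
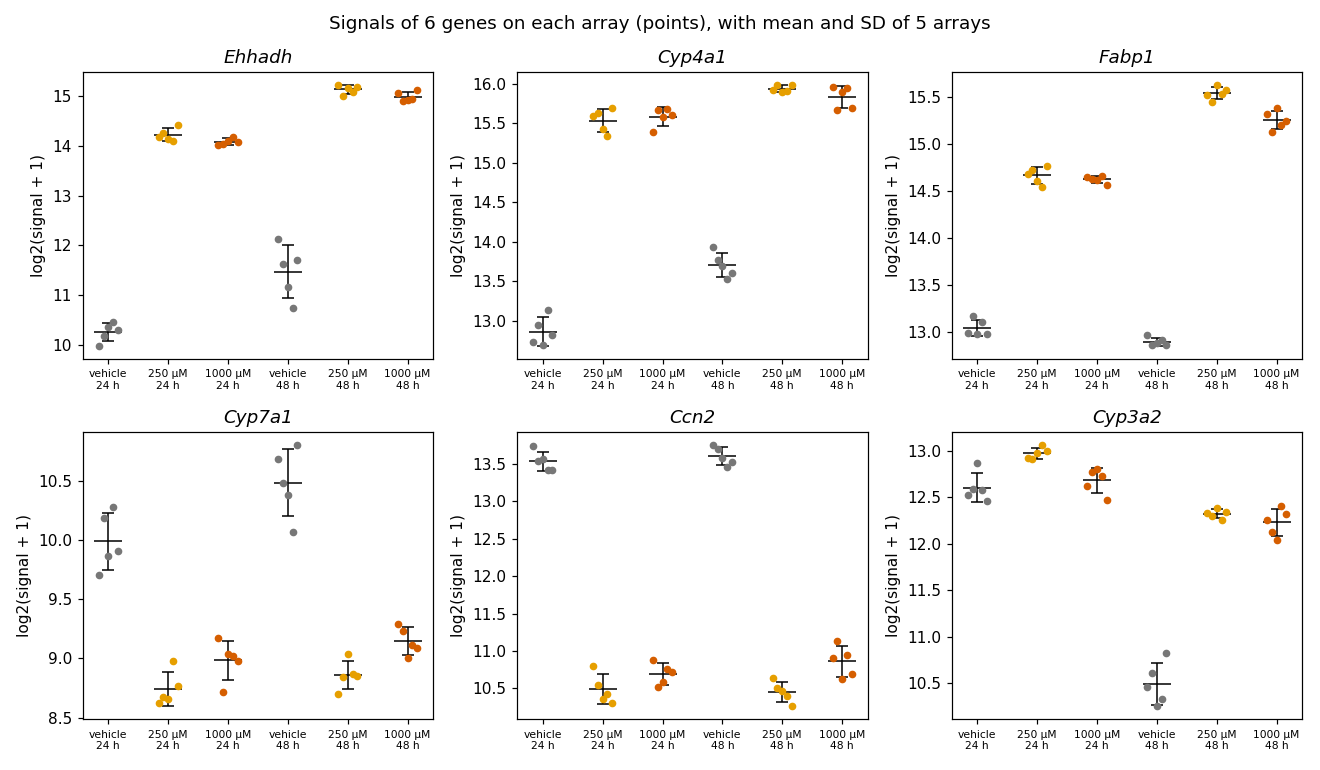
Log2 signal of 6 genes on each array (points), with the mean and SD of 5 arrays per group. Ehhadh, Cyp4a1 and Fabp1 lie higher in all treated arrays than in vehicle of the same time, and Cyp7a1 and Ccn2 lower, while Cyp3a2 is lower in vehicle at 48 h than at 24 h.

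The doses were compared directly to ask whether 1000 µM had another effect than 250 µM. At 24 h, Mx2 (-0.88 ± 0.16) and Isg15 (-0.76 ± 0.14), both induced by interferons, were lower at 1000 µM, and they were the only 2 of 10528 genes called by limma (adjusted p = 0.0207 for both), while 335 had an unadjusted p under 0.05 where chance gives 526. At 48 h, 7 genes differed: Ints7 (1.43 ± 0.26), Masp1 (0.49 ± 0.10) and Cdh2 (0.34 ± 0.06) were higher at 1000 µM, as was Cab39 (0.30 ± 0.06), which lies outside the naming rule and was chosen after its value was seen, and Rup2 (-0.43 ± 0.06), Mrpl27 (-0.30 ± 0.05) and Fabp1 (-0.29 ± 0.05) were lower. An unadjusted p under 0.05 was reached by 1297 genes at 48 h. The 95% interval of the difference between doses lay within 1 log2 unit of 0 for 96.1% of genes at 24 h and 96.3% at 48 h. It lay within 0.5 of 0 for 76.4% and 72.9%. For Ehhadh it ran from -0.43 to 0.15 at 24 h and from -0.43 to 0.14 at 48 h, and for Cyp4a1 from -0.12 to 0.22 and from -0.27 to 0.06. Cyp4a1 lay at 15.90 to 15.99 and 15.67 to 15.97 on the log2 scale at 250 and 1000 µM and 48 h, where the highest signal of any gene was 16.44 and 16.39. A ceiling on its signal is therefore not excluded, and it would hide a dose difference and lower the effect at 48 h. Leaving out 1 array gave 0 to 3 genes at 24 h and 1 to 20 at 48 h, and array weights gave 409 at 48 h.

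At 48 h the fatty acid lists were lower at 1000 than at 250 µM at the preset correlation, with medians of -0.13 for the mitochondrial, -0.15 for the peroxisomal and -0.09 for the PPARα list (camera adjusted p = 4.4e-09, 3.9e-08 and 7.2e-05), and the calls were lost otherwise (adjusted p = 0.114, 0.114 and 0.116 with an estimated correlation). Of their members 0, 0 and 1 fell (3, 4 and 2 adjusted over the list alone, with 1 rise in the PPARα list). Hepatocyte markers (0.00682), NRF2 targets (0.00780) and drug metabolism genes (0.0460) also passed camera downward, and p53 targets (0.0460) upward, with 0 members called in each over all genes. The p53 targets had 6 higher and 1 lower adjusted over the list alone. None of these 4 passed with an estimated correlation (adjusted p = 0.616, 0.168, 0.441 and 0.114 with an estimated correlation). At 24 h cholesterol synthesis and bile acid genes passed upward (camera adjusted p = 0.00207 and 0.0156) and lost the call otherwise (adjusted p = 0.273 and 0.584 with an estimated correlation), with 0 members called in either (0 and 1 adjusted over the list alone).

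In vehicle, 48 h was compared with 24 h, where culture time and the actin and Gapdh ratios differ together. Scd2 (2.54 ± 0.11), a fatty acid desaturase, Ucp2 (2.14 ± 0.30), Gtf3c1 (1.74 ± 0.47), Tgfb2 (1.68 ± 0.24), a TGF-β ligand, and Lamb3 (1.61 ± 0.15), a laminin chain, rose most. Serpina6 (-2.52 ± 0.11), corticosteroid-binding globulin, Serpina3c (-2.43 ± 0.09), Il1rn (-2.28 ± 0.28), the interleukin-1 receptor antagonist, Gstp3 (-2.13 ± 0.35) and Cyp3a2 (-2.11 ± 0.09), a drug-metabolising cytochrome, fell most. 2963 of 10528 genes changed, 1731 upward and 1232 downward (limma). This comparison rests on the arrays of raised actin ratio: without the 4 of them 146 genes changed (65 upward and 81 downward) and with the ratio as a covariate 749, against 1080 to 2217 with each of the 4 as the only vehicle array at 48 h. Without them Ucp2 (1.14), Gtf3c1 (1.16) and Tgfb2 (1.51) did not pass. The 24 h mean of Ucp2 and the 48 h means of Gstp3 and Il1rn lay under the low-signal limit, and the changes counted from it were 0.31, -1.17 and -1.94. With array medians centred 1692 genes rose and 469 fell. Every probe set on its own gave 4638 calls, and a fit of the 2 vehicle groups alone 1902.

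Of 20 cholesterol synthesis genes 13 rose and 1 fell (15 and 1 adjusted over the list alone) with time in vehicle (camera adjusted p = 4.4e-06, adjusted p = 0.0255 with an estimated correlation), and of 18 fatty acid synthesis genes 11 rose and 0 fell (13 and 0 adjusted over the list alone) (camera adjusted p = 7.2e-07, adjusted p = 0.0255 with an estimated correlation). Without the 4 arrays 3 and 1 of these rose, with median changes of 0.25 and 0.20, and both lists passed (adjusted p = 0.0115 and 0.0179 with an estimated correlation). In the PPARα list 14 rose and 1 fell (15 and 1 adjusted over the list alone) of 25 (camera adjusted p = 2.9e-06, adjusted p = 0.0507 with an estimated correlation). Hepatocyte markers had 1 rose and 9 fell (1 and 9 adjusted over the list alone) of 27 (camera adjusted p = 1.5e-05, adjusted p = 0.429 with an estimated correlation), CAR and PXR regulated genes 5 rose and 9 fell (5 and 10 adjusted over the list alone) of 20 (camera adjusted p = 0.0443, adjusted p = 0.429 with an estimated correlation), AhR targets 0 rose and 1 fell (0 and 1 adjusted over the list alone) of 5 (camera adjusted p = 0.0476, adjusted p = 0.245 with an estimated correlation) and Kupffer cell and leukocyte markers 0 rose and 3 fell (0 and 7 adjusted over the list alone) of 10 (camera adjusted p = 0.0111, adjusted p = 0.0507 with an estimated correlation). With an estimated correlation the PPARα list passed without the 4 arrays and with the covariate (adjusted p = 0.0481 and 0.0374), as did CAR and PXR regulated genes with the covariate (0.0460, against 0.0696 without the arrays). Cholangiocyte markers passed upward without the arrays (0.0481).

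Whether each dose acted differently at 48 than at 24 h was tested as a difference of effects. Cyp3a2 (1.45 ± 0.12) had the largest upward difference at 250 µM, followed by Btc (1.45 ± 0.42) and Tdh (1.44 ± 0.32), and Il1r2 (-3.36 ± 0.38), Syn1 (-2.10 ± 0.49) and Mul1 (-1.99 ± 0.47) the largest downward ones. At 1000 µM these were Cyp3a2 (1.66 ± 0.12), Cxcl9 (0.94 ± 0.15) and Spc24 (0.93 ± 0.13) upward and Il1r2 (-2.70 ± 0.38), Npy (-1.31 ± 0.20) and Gpx8 (-1.17 ± 0.26) downward. The log2 signal of Cyp3a2 in vehicle was 12.46 to 12.87 at 24 h and 10.26 to 10.82 at 48 h. It was 12.91 to 13.06 and 12.26 to 12.39 at 250 µM, and 12.47 to 12.81 and 12.04 to 12.41 at 1000 µM. Its upward difference is thus a smaller fall with time than in vehicle. The means of Il1r2, Syn1 and Mul1 at 250 µM and 48 h and of Il1r2 at 1000 µM and 48 h lay under the low-signal limit, so these differences are uncertain in size, and counted from the limit they were -2.43, -1.60 and -1.48, and -2.58. At 250 µM 880 genes differed (404 upward, 476 downward) and at 1000 µM 102 (55 upward, 47 downward, limma). Both counts were far lower with array medians centred and far higher with array weights, as the section on processing gives. Without the 4 vehicle arrays the counts were 58 and 38, against 336 to 1165 and 30 to 432 with each of the 4 as the only vehicle array at 48 h, so the drop at 1000 µM is no larger than the loss of arrays gives. The upper ends of both ranges come from vehicle replicate 1, and at 1000 µM replicates 2, 3 and 5 lay near the lower end. With the actin covariate the counts of differing genes were 248 and 74. Without the 4 arrays Btc (0.08), Tdh (1.77), Syn1 (-2.39), Mul1 (-0.91), Cxcl9 (0.47) and Gpx8 (-1.12) did not pass, and with the covariate Btc (0.69) and Mul1 (-1.73) did not. Leaving out vehicle replicate 4 at 48 h gave 1789 and 322. At 1000 µM the count was 203 without vehicle replicate 1 at 24 h, 63 without vehicle replicate 4 at 24 h, 65 without 1000 µM replicate 3 at 24 h, 64 without vehicle replicate 3 at 48 h, and 64 and 65 without 1000 µM replicates 3 and 5 at 48 h. The cholesterol list passed upward for both doses, with medians of 0.24 and 0.20 (camera adjusted p = 2.6e-06 and 2.2e-06, adjusted p = 0.0264 and 0.0251 with an estimated correlation). With all 30 arrays other lists passed at the preset correlation only. At 250 µM these were the mitochondrial, peroxisomal, drug metabolism and NRF2 lists upward and the acute phase list downward (camera adjusted p = 1.6e-04, 0.00268, 0.00268, 0.00268 and 0.0369, against 0.275, 0.475, 0.275, 0.275 and 0.475 with an estimated correlation). At 1000 µM they were the drug metabolism, NRF2 and fatty acid synthesis lists upward and the heat shock, acute phase and dedifferentiation lists downward (camera adjusted p = 0.00318, 0.00318, 0.0169, 0.0341, 0.0175 and 0.0389, against 0.239, 0.170, 0.355, 0.130, 0.355 and 0.406 with an estimated correlation). With an estimated correlation and the actin covariate the mitochondrial, PPARα, drug metabolism, NRF2, cholesterol and fatty acid synthesis lists passed upward at 250 µM (adjusted p = 0.0131, 0.0482, 0.0131, 0.0131, 0.0124 and 0.0290), as they did without the 4 arrays (0.0266, 0.0266, 0.0266, 0.0266, 0.0189 and 0.0189). At 1000 µM the drug metabolism, NRF2, cholesterol and fatty acid synthesis lists passed with the covariate (0.0163, 0.0163, 0.0163 and 0.0163), and without the 4 arrays fatty acid synthesis alone (0.0143, with 0.103 for cholesterol).

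**Figure D4:**
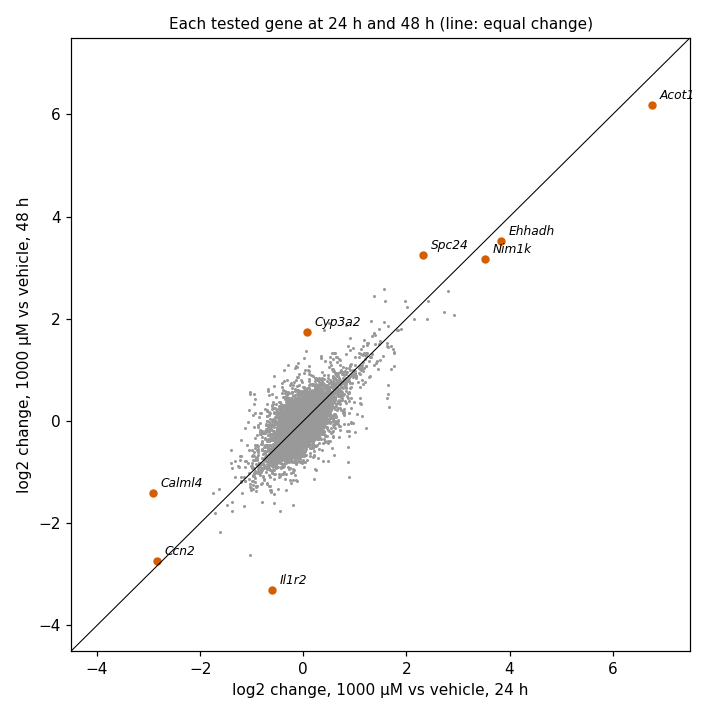
Log2 change at 1000 µM against vehicle of each tested gene at 24 h (horizontal) and at 48 h (vertical), with the line of equal change and 8 named genes. Ehhadh, at 3.83 and 3.52, lies near the line, and Il1r2, at -3.31 at 48 h, lies far below it.

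Genes called at both times were far more than independent calls would give. At 250 µM 653 genes rose at both times (133 for independent calls), 906 fell at both (300.4) and 26 went opposite ways. At 1000 µM 647 rose (100.0), 885 fell (216) and 7 went opposite ways. These comparisons share no arrays, but their tests share each gene's variance estimate. That alone can raise the number of genes called at both times, so the numbers for independent calls are a rough guide. It would raise opposite calls too, for which independent calls would give 403.5 at 250 µM and 294.6 at 1000 µM. Across genes, which are not independent replicates, Pearson's r between the times was 0.685 at 250 µM and 0.714 at 1000 µM. Between the doses 736 genes rose and 909 fell at both doses at 24 h, and 1093 and 1729 at 48 h, with 0 opposite at either time. The r across genes between doses was 0.888 at 24 h and 0.910 at 48 h. As the doses share vehicle arrays, simulated data with no effect gave 0.50 and 0.497, and with the vehicle arrays split between the doses the genes shared in direction numbered 983 at 24 h and 1879 at 48 h on average, with fewer vehicle arrays behind each dose, and r was 0.630 and 0.744.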

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

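The tests of the vehicle arrays at 48 h, of gene selection and of Spc24 were chosen after the result was seen, while the other groupings of the arrays and the tests of signal range and RNA quality at 1000 µM were chosen before. Of 72 groups of 5 values tested for a single array far from the others, 2 had one, where chance gives 3.6. Replicate 3 at 1000 µM and 24 h had an actin ratio of 1.30, with a gap of 0.725 of the group's range, and replicate 4 at 250 µM and 24 h had the lowest Pdk4 signal of its group, 15 on the log2 scale, with a gap of 0.764. Probe sets that named no gene or several were outside the comparisons, and 549 of them changed at 250 µM and 550 at 1000 µM at 24 h, and 1134 and 748 at 48 h.

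The effect of 250 µM differed between 48 and 24 h in 58 of the 153 genes given in this text (limma, test of the difference itself, log2). Of these Acot12, Acot13, Cab39 and Usp18 lie outside the naming rule and were chosen after their values were seen. It was higher at 48 h for Cyp3a2 (1.45), Btc (1.45), Tdh (1.44), Cxcl9 (1.27), Spc24 (1.13), Fabp1 (1.02), Aqp7 (0.91), Slc30a1 (0.83), Pnpla3 (0.81), Fads1 (0.76), Acot8 (0.72), Otc (0.67), Acot12 (0.64), Abcg5 (0.63), Msmo1 (0.57), Tk1 (0.57), Asgr1 (0.53), Cebpa (0.44), Gsta4 (0.41), Cyp2c6v1 (0.41), Idi1 (0.38), Fdft1 (0.36), Ces2c (0.35), Nsdhl (0.35), Tm7sf2 (0.34), Acot13 (0.34), Acadm (0.32), Mrpl27 (0.30) and Akr7a3 (0.26). It was lower at 48 h for Il1r2 (-3.36), Syn1 (-2.10), Mul1 (-1.99), Ucp2 (-1.77), Isg15 (-1.40), Npy (-1.35), Ints7 (-1.27), A2m (-1.12), Lamb3 (-1.05), S100a6 (-1.0), Slc7a11 (-0.82), Steap4 (-0.79), Usp18 (-0.74), Lox (-0.74), Masp1 (-0.73), Gucy2c (-0.73), Icam1 (-0.72), Cryab (-0.61), Ahsg (-0.58), Cp (-0.57), Ccng1 (-0.56), Aen (-0.55), Serpina3n (-0.51), Cab39 (-0.45), Cyp4a1 (-0.44), Vim (-0.42), Cyp1a2 (-0.36), Cdh2 (-0.31) and Tpm4 (-0.27). In 4 of these a group mean lay under the low-signal limit of 7.88. Counted from the limit the differences were -2.43 for Il1r2, -1.60 for Syn1, -1.48 for Mul1 and 0.06 for Ucp2, so no difference between times is taken as shown for Ucp2.

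The list for 250 µM depends on the 4 vehicle arrays of raised actin ratio at 48 h, though leaving them out also removes replicates. Without them 17 of the 58 passed, namely A2m, Acot8, Ahsg, Aqp7, Cryab, Cxcl9, Cyp3a2, Fabp1, Fads1, Il1r2, Isg15, Npy, S100a6, Serpina3n, Spc24, Steap4 and Usp18, and with the ratio as a covariate 34. Less than 50% of the difference remained without them for Btc (0.08), Cdh2 (-0.10), Idi1 (0.13), Mul1 (-0.91), Slc30a1 (-0.11) and Ucp2 (-0.77). Of all 880 genes called, 44 were called without them as well.

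The effect of 1000 µM differed between the times in 22 of these genes. It was higher at 48 h for Cyp3a2 (1.66), Cxcl9 (0.94), Spc24 (0.93), Fabp1 (0.78), Fads1 (0.74), Aqp7 (0.66), Cebpa (0.61), Tk1 (0.48), Acot8 (0.48), Asgr1 (0.42) and Tm7sf2 (0.41). It was lower at 48 h for Il1r2 (-2.70), Npy (-1.31), Gpx8 (-1.17), S100a6 (-1.05), Lamb3 (-0.81), A2m (-0.79), Cyp4a1 (-0.59), Cryab (-0.52), Ahsg (-0.45), Ccng1 (-0.34) and Serpina3n (-0.34). The 1000 µM mean of Il1r2 lay under the limit, and counted from it the difference was -2.58. Without the 4 arrays 10 of the 22 passed, namely Acot8, Cebpa, Cryab, Cyp3a2, Fabp1, Fads1, Il1r2, Npy, S100a6 and Spc24, and with the covariate 17. Less than 50% remained without them for Asgr1 (0.21), Cxcl9 (0.47) and Lamb3 (-0.30). Of all 102 genes called, 18 were called without them as well.

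Other groupings of the same arrays, 100 per comparison with the real one, were used to ask whether chance can be excluded. In 8 comparisons 1 grouping, the real one, gave as many genes, without adjustment over the comparisons. This is the lowest result the test can give. By it chance is taken as excluded in the comparisons of a dose with vehicle. For time in vehicle, where the highest other count came near the real one, it argues against chance only. The real count and the highest other were 2030 and 563 at 250 µM and 2051 and 707 at 1000 µM at 24 h, and 4342 and 3558 at 250 µM and 3132 and 2077 at 1000 µM at 48 h. They were 2 and 1 between doses at 24 h, 7 and 1 between doses at 48 h, 2963 and 2830 for time in vehicle, and 880 and 862 for the difference between times at 250 µM. Between doses at 24 h other values bear against excluding chance: 335 genes had an unadjusted p under 0.05 where chance gives 526. Leaving out any of 6 arrays left 0 calls there, so chance is not taken as excluded. Between doses at 48 h leaving out 1 array gave 1 to 20 genes, so that count is not stable and chance is not taken as excluded there either. For the difference between times at 1000 µM 2 of 100 groupings gave as many genes, with 102 genes in the real one and 682 in the highest other. Why that grouping called several times the real count was not tested. For both differences between times the groupings exchanged vehicle and treated arrays within each time. They ask whether treatment had any effect, not whether its effect differed between times. Chance is therefore not taken as excluded for either difference.

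More genes differed from vehicle at 48 h (4342 at 250 and 3132 at 1000 µM) than at 24 h (2030 and 2051), and 4 of 5 vehicle arrays at 48 h had a raised actin ratio. At 1000 µM and 48 h the median log2 change of the fatty acid lists was 0.96 with the ratio as a covariate and 0.88 without it, a quotient of 1.09. These values argue against a rise of the lists through RNA quality as the actin ratio gives it. The test replaced one on replicate 4 alone, as 1 array excludes nothing, but it is not free of that array. The covariate's slope comes from differences within groups, which were largest in vehicle at 48 h (SD 0.494, against 0.0783 to 0.157 elsewhere). There replicates 1 (2.44) and 4 (1.04) lay at the ends, so the slope rests largely on these arrays. Replicate 4 lay at 0.721 between the 24 h vehicle mean (0) and the other 48 h vehicle arrays (1). The highest 24 h vehicle array lay at 0.0898 (SD 0.0455) and the other 48 h vehicle arrays at 0.936 to 1.05, so it was outside both ranges. Its distance from the 24 h arrays argues against a 24 h culture under a wrong label. However, a first bound of 0.75 was missed and the bound used was set with the value known. Genes whose 250 µM effect differed between times, chosen without replicate 4, retained 0.296 of their difference when that array alone stood for vehicle at 48 h. Each other array, treated in the same way, gave 0.987 to 1.08. The share of 0.296 goes with RNA quality as the cause of most of the differences between times, wording narrowed from the whole cause once the value was known. It cannot settle this, as it rests on 1 array that had already stood apart and may differ in other ways. With the actin ratio as a covariate fewer genes differed, but of the 58 given in this text 34 passed and 2 lost most of their difference. It stays open whether replicate 4 or the other 4 arrays show vehicle cells at 48 h better, and a biological difference between times remains untested apart from them.

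At 48 h the response at 1000 µM was smaller than at 250 µM: the score over genes called at both doses at 24 h was 1.04 ± 0.0202 and 1.17 ± 0.0181 (SD, n = 5), a ratio of 0.889. Selection on the same arrays is argued against, as these genes were chosen at 24 h and the exact two-sided permutation p was 0.00794, the smallest that 5 against 5 can give, while genes chosen at 48 h gave 0.702 and 0.706 at 24 h (exact p = 0.762). Compressed signals are argued against by a ratio of 1.01 (SE 0.0294) in the interquartile range over genes with no 24 h response. RNA quality of these arrays, as the actin ratio gives it, is argued against by a difference of -0.13 with the actin covariate and -0.13 without it, a quotient of 1.02. That covariate's slope too rests largely on vehicle replicates 1 and 4 at 48 h. A smaller response to the higher dose may therefore be biological, as a hypothesis found and tested on the same arrays, and the amount of compound in solution was not measured.

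The Spc24 probe set rose in all 4 comparisons with vehicle, by 3.25 ± 0.09 at 1000 µM and 48 h. More dividing cells as the cause of the whole rise are argued against, since 19 other genes of its complex and the cell cycle list past the filter, Ccnd1 included, had a median log2 change of 0.27 (SD 0.37, highest 1.0) and 2 rose; a smaller rise in dividing cells stays open. This test replaced a first one that left out Ccnd1 and kept genes of low signal. Signal from the transcript of a neighbouring gene stays open: of 7 measured genes among the 5 on either side, Angptl8 rose most, by 1.07, and Kank2 by 0.76, both named after their values were seen, and genes there without a value were not tested. A test on other probe sets of Spc24 was planned and void, as there are 0. No biological explanation was tested.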

How the results depend on the processing

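The alternatives without the 4 vehicle arrays of raised actin ratio and with the ratio as a covariate were chosen after seeing the data, the others before. With array medians centred the counts of changed genes were 1327 at 250 µM and 1284 at 1000 µM at 24 h, 0 and 2 between doses at 24 and 48 h, and 150 and 16 for the difference between times at 250 and 1000 µM. Every probe set on its own, a setting that tests more features, gave 6556 at 250 µM and 48 h, 4638 for time in vehicle and 13 between doses at 48 h. The mean of a gene's probe sets gave 1 and 3 between doses at 24 and 48 h. A fit of the compared groups alone, with fewer arrays behind each variance, gave 4 and 3 between doses, 1902 for time in vehicle and 36 for the difference between times at 1000 µM. Array weights gave 4 and 409 between doses and 2118 and 295 for the differences between times. Without the mean-variance trend there were 0 genes between doses at 24 h (0 where limma with the trend called 2) and 65 for the difference between times at 1000 µM, which was 156 with quantile normalization. Without the 4 vehicle arrays the counts were 1380 and 1177 at 250 and 1000 µM at 48 h, 1 and 13 between doses, 146 for time in vehicle, and 58 and 38 for the differences between times. With each of the 4 as the only vehicle array at 48 h the counts were 2194 to 3034 and 1311 to 2199 at 250 and 1000 µM at 48 h, 1080 to 2217 for time in vehicle, and 336 to 1165 and 30 to 432 for the differences between times. With the actin covariate they were 2782 at 250 µM and 48 h, 749 for time in vehicle and 248 for the difference between times at 250 µM. Except where a construction is named, the cause was not tested. Other alternatives kept these counts within 1.5 times.

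Leaving out 1 array gave 1831 to 1953 and 1818 to 1955 changed genes at 250 and 1000 µM at 24 h, 3979 to 4683 and 2690 to 3599 at 48 h, and 2425 to 3690 for time in vehicle. For the difference between times it gave 609 to 1789 at 250 µM, the highest without vehicle replicate 4 at 48 h, and 63 to 322 at 1000 µM, the highest without the same array. Between doses at 24 h it gave 0 to 3: 0 without 250 µM replicate 1 or 1000 µM replicate 1 or 250 µM replicate 2 or 1000 µM replicate 2 or 1000 µM replicate 4 or 1000 µM replicate 5, 1 without 250 µM replicate 3 or 1000 µM replicate 3 or 250 µM replicate 4, and 3 without 250 µM replicate 5. Between doses at 48 h it gave 1 to 20: 1 without 1000 µM replicate 2 or 250 µM replicate 3, 2 without 250 µM replicate 5, 4 without 1000 µM replicate 1 or 250 µM replicate 4 or 1000 µM replicate 4, 15 without 250 µM replicate 1 and 20 without 1000 µM replicate 3.

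The upward share of calls moved by over 10 points in the following cases. With the 4 vehicle arrays left out it went from 36.9% to 49.9% at 250 µM and from 38.5% to 52.4% at 1000 µM at 48 h, from 58.4% to 44.5% for time in vehicle, and from 45.9% to 62.1% and 53.9% to 73.7% for the differences between times at 250 and 1000 µM. With the actin covariate the last 2 were 64.5% and 66.2%, and without vehicle replicate 1 at 48 h the last was 64.8%. With array medians centred it went from 42.5% to 52.7% at 1000 µM and 24 h (677 up, 607 down), from 58.4% to 78.3% for time in vehicle (1692 up, 469 down), and from 53.9% to 37.5% for the difference between times at 1000 µM (6 up, 10 down). Between doses, where 2 and 7 genes were called and a few genes shift the share, quantile normalization gave 7 up and 3 down at 48 h and 1 up and 2 down at 24 h, and every probe set on its own 1 up and 2 down and array weights 1 up and 3 down at 24 h. At 48 h no filter gave 2 up and 3 down, every probe set on its own 6 and 7, the mean of probe sets 1 and 2, the compared groups alone 0 and 3, the set without the 4 arrays 6 and 7, the covariate 2 and 4, and leaving out 1 array moved the share by over 10 points for 9 of 10 arrays of these groups. The median change of all genes stayed within 0.1 of 0 under each scaling.

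Of the log2 changes of named genes (436 in their comparisons), the only reversals were those of Slc30a1, at -0.11 for 250 µM and -0.13 for 1000 µM at 48 h without the 4 vehicle arrays, where neither passed. That setting ended 47 further calls, the actin covariate 17, centring 22 and a fit of the compared groups 19. Of the leave-one-out values 4370 kept their side of the threshold, 107 lost a call and 3 gained one. Of 152 other probe sets of named genes that changed, 81 were called in the same direction and 0 in the opposite one, while 52 and 19 with the same and the opposite sign were not called. In 26 of 95 cases no other probe set was called, such as Sesn1 at 48 h (0.09 at 250 µM, -1.32 for the one used) and Tpm4 at 48 h (-0.17 at 250 µM, -0.98 for the one used) and Cdc20 at 1000 µM and 24 h. Of 92 list results, the estimated correlation ended 15 calls, quantile normalization ended 1 and added 2, centring added 1, and the block changed 0. Fry, which asks whether a list's genes move without comparing them to others, added 39 in 1 direction and 44 in either. Among results that passed in either setting, no list reversed its direction where the setting gives one. For lists and named genes alike, a change of sign where neither setting passed was not counted as a reversal.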

Other observations

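The single genes of this and the next paragraph lie outside the naming rule and were chosen after their values were seen. Acot4 and Pex19 belong to the peroxisomal list, which was tested as a whole, and the others were tested as no group and stand for none. Among acyl-CoA thioesterases, at 1000 µM and 24 h, the log2 changes were Acot3 (1.64 ± 0.08), Acot4 (1.46 ± 0.09), Acot12 (1.37 ± 0.09), Acot7 (1.15 ± 0.09) and Acot13 (0.31 ± 0.06), and Acot9 (-0.05 ± 0.06) did not pass. At 48 h they were Acot12 (1.72 ± 0.09), Acot4 (1.51 ± 0.09), Acot3 (1.46 ± 0.08), Acot7 (0.81 ± 0.09) and Acot13 (0.50 ± 0.06), and Acot9 (-0.15 ± 0.06) did not pass. The other probe set of Acot7 was not called at 1000 µM, with 0.29 at 24 h and -0.41 at 48 h. At 250 µM Acot3 had 1.79 ± 0.08 at 24 h and 1.56 ± 0.08 at 48 h, and Acot12 1.33 ± 0.09 and 1.97 ± 0.09. As Acot1 to Acot4 are close relatives, their probe sets could share signal, which was not tested; for the same reason the log2 change of Acot1 itself (6.18 at 1000 µM and 48 h with quantile normalization) is not assigned to 1 copy.

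At 1000 µM and 24 h the values of 4 further genes were Pex19 (0.74 ± 0.08), Pex16 (0.62 ± 0.10), Pex3 (0.37 ± 0.08) and Pex13 (0.32 ± 0.06), and at 48 h Pex19 (0.92 ± 0.08), Pex16 (0.66 ± 0.10), Pex3 (0.38 ± 0.08) and Pex13 (0.36 ± 0.06). The other probe set of Pex16 was not called, with 0.11 at 24 h and 0.14 at 48 h. The values of Ccn1 and Tgfbi at 1000 µM were -0.84 ± 0.17 and -0.52 ± 0.08 at 24 h and -0.86 ± 0.17 and -0.55 ± 0.08 at 48 h. Usp18, an interferon-induced gene like Isg15 and Mx2, had -0.50 ± 0.10 for 1000 against 250 µM at 24 h and did not pass (adjusted p = 0.0545, limma).

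Among the 4513 probe sets that passed the filter and had no gene or several genes, 12.2% changed at 250 µM and 24 h, 12.2% at 1000 µM and 24 h, 25.1% at 250 µM and 48 h and 16.6% at 1000 µM and 48 h. Probe sets with 1 gene changed in 16.7%, 17.1%, 38.4% and 26.6% under the same test of every probe set.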
